A study of Mus musculus with 3 samples.

How the data were processed

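The count matrices are as deposited by the authors, who made them before submission with Cell Ranger 5.0.1, STAR 2.7.2a and the mm10 mouse genome, by the submitters' processing notes, which do not give the role of each tool. Each matrix holds UMI counts of 32285 genes in barcodes that the authors had already called as cells, so droplets without cells were not available to measure free RNA directly. Together the 3 matrices hold 21947 barcodes and 87244310 UMIs. Sequencing reads were not used here.

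A barcode was kept with at least 200 detected genes, at least 500 UMIs and at most 10% mitochondrial UMIs, which removed 15 barcodes at 0 µm, 3 at 4 µm and 29 at 90 µm. Scrublet as built into scanpy called doublets in each library, and 69, 120 and 172 barcodes (1.14%, 1.79% and 1.89%) were removed before clustering. Its approximate neighbour search failed in the 90 µm library, so exact neighbours were used for all 3, a choice made after seeing the data. Doublets of 2 cells of one type are not seen by this caller. The 21539 kept cells were scaled to 10000 UMIs, log-transformed, reduced to 2000 variable genes and 30 principal components, and grouped with Leiden clustering (15 neighbours, resolution 1) into 21 clusters without correction between libraries. A cluster made up mostly of 1 library may reflect that library and not a cell type.

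Clusters were named from markers fixed in advance: a class needed at least 3 markers each seen in at least 10% of the cluster's cells, and the runner-up class had to score under 0.6 of the best. These thresholds, and the rule for T subclusters, were set after seeing the data. T-like cells were clustered again with 20 components. Shares of cells carry exact Clopper-Pearson intervals, and ratios of shares or of gene levels exact conditional binomial intervals. Both treat cells or UMIs as independent, which they are not within a mouse or a cell, so true errors are larger. Because each surface has 1 library, no p-values or counts of differing genes are given.

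UMIs of all cells of a class were summed per library and divided by the class total to give CPM. A ratio was given for a class with at least 100 cells in both libraries. Where a library had 0 UMIs of a gene, a floor of 3 counts in that library gives the least fold, the upper 95% limit of a count of 0. This fold leaves out the counting error of the other library, which the exact lower limit printed beside it holds. Named genes are the 5 highest and 5 lowest ratios per class and comparison among genes with at least 50 UMIs and 50 CPM in the higher library, and with a mean level over the 3 libraries of at least 0.5 of the highest mean in any other class, which leaves out genes that free RNA of another class could bring. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin and T cell receptor segment genes and genes with only a model or clone name were left out. From 1272 to 1345 genes met this in neutrophil-like and from 1916 to 1984 in monocyte/macrophage-like cells. A minimum of 200 UMIs left out no gene, since 50 CPM is already more UMIs than that in these class sums, so it shows nothing about stability. Without the limit on other classes, between 2 and 5 of each 5 were shared. In addition, 16 genes chosen in advance and members of the gene lists could be named.

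There are 21 gene lists, written from general knowledge; 12 were read in monocyte/macrophage-like cells and 14 in T-like cells. For each list the median log2 ratio over members with at least 30 UMIs across the libraries is given, with 0.5 UMIs added, an interval from 2000 Poisson bootstrap draws, and its percentile among 10000 random lists whose members were drawn from the 100 genes nearest in mean expression. The percentile describes these libraries and is not a test. A member at 0 UMIs in 1 library was also set to its 3-count bound, and members with at most 3 UMIs in both were left out, to see whether the median held. In total, 2 list genes had no entry in the matrices. Reading 4 lists in neutrophil-like and 4 in dendritic-like cells, and the T lists between 90 and 4 µm alone, was decided after seeing the data.

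Shares of T-like cells with a UMI of a gene were taken after thinning each cell to 1000 UMIs at random, leaving out cells with fewer, and also at 2000 UMIs and unthinned. Alternatives fixed in advance were a stricter cell filter (500 genes, 1000 UMIs, 5% mitochondrial), no filter, doublets kept, resolutions 0.5 and 2, 15 components, naming each cell by markers without clusters, median-of-ratios and edgeR TMM scaling, the mean over cells of each cell's CPM, list minimums of 200 and 1 UMIs, and 1 UMI added. Weighting each library to one mix of clusters, over clusters with at least 20 cells in each library (for T-like cells, in the 4 and 90 µm libraries), and the stricter filter for lists were added later.

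As a self-test, counts were simulated at the depth of the monocyte/macrophage-like sums with known folds set in 200 genes, 50 at each of 0.5-, 1.5-, 2- and 4-fold. For 4 over 0 µm (10148 genes), intervals held the truth in 95.8% of unchanged genes, and the direction was recovered in 92%, 90%, 100% and 100% of genes at these folds. For 90 over 0 µm (10043 genes) the values were 95.9%, and 98%, 96%, 94% and 100%; for 90 over 4 µm (10642 genes) 95.7%, and 98%, 100%, 100% and 100%. A list of 15 genes at 2-fold gave medians of 0.96, 0.95 and 0.97 in log2 at percentile 100, and 15 unchanged genes gave -0.06, -0.08 and -0.05 at percentiles 17.0, 25.4 and 31.2. These simulations hold counting error and no difference between mice.

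Gene positions were matched by Ensembl ID to GENCODE vM21, with 240 of 240 genes wanted found. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.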

Results

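Single-cell RNA sequencing was done on non-adherent immune cells washed out of the fibrous capsule that forms around silicone implants. Small implants of 1.3 cm with a surface topology of 0, 4 or 90 µm had been placed in the mammary fat pad of C57BL/6 mice, a common inbred laboratory strain, and tissue was taken after 2 weeks. Each surface has 1 library, and each library holds the cells of 5 mice pooled together. The spread between mice or between libraries of one surface is therefore unmeasured, no test between surfaces was possible, and every difference below is a difference between 3 libraries. All intervals are 95% intervals and cover counting error only. The 0 µm library held 6088 barcodes and 18064259 UMIs (unique molecular identifiers, one per captured transcript), the 4 µm library 6726 barcodes and 28402336 UMIs, and the 90 µm library 9133 barcodes and 40777715 UMIs. Median depth per barcode was 2350 UMIs at 0 µm, 3332 at 4 µm and 3238 at 90 µm. After filtering and removal of called doublets, 6004, 6603 and 8932 cells were kept.

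The study's title asks how the topography of an implant's surface relates to the foreign body response, and the first comparison sets the makeup of the washed-out cells side by side for the 3 surfaces. Neutrophil-like cells were the largest class at 0 µm, with 62.6% of kept cells (61.4 to 63.8), and made up 38.7% (37.5 to 39.8) at 4 µm and 47.7% (46.6 to 48.7) at 90 µm. Monocyte/macrophage-like cells, the class of phagocytes that settle on implants, were 30.5% (29.4 to 31.7), 52.4% (51.2 to 53.6) and 32.5% (31.5 to 33.5). At 0 µm, 58.7% of this class lay in cluster 1, with a median of 933 UMIs per cell there. That cluster had the lowest marker score of the 21 clusters, so its name is weakly based. With the stricter cell filter the class was 24.95%, 49.49% and 30.67% of cells. T-like cells were 4.62 times as large a share at 90 µm as at 0 µm (3.70 to 5.84) and 2.79 times the share at 4 µm (2.35 to 3.34). B-like cells were 17.9 times the 0 µm share (9.86 to 36.3) and 6.19 times the 4 µm share (4.35 to 9.06).

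In cells, the T-like class numbered 89 of 6004 at 0 µm (1.48%), 162 of 6603 at 4 µm (2.45%) and 612 of 8932 at 90 µm (6.85%). B-like cells numbered 11, 35 and 293, or 0.183%, 0.530% and 3.28%. Dendritic-like cells, which present antigen to T cells, were 3.18%, 4.41% and 7.55%, a ratio of 2.37 (2.02 to 2.80) for 90 µm over 0 µm and of 1.71 (1.49 to 1.97) for 90 µm over 4 µm. With classes set cell by cell from markers, these dendritic-like ratios were smaller, at 1.52 and 1.15. NK-like cells were 0.816%, 0.9995% and 1.52%. Plasmacytoid dendritic-like cells were rare, at 0.183%, 0.121% and 0.179%. Shares of one library sum to a whole, so a lower share of one class raises the others. Among cells outside the neutrophil-like class, T-like cells still took 13.1% (12.1 to 14.1) at 90 µm against 3.96% (3.20 to 4.86) at 0 µm and 4.00% (3.42 to 4.65) at 4 µm. Monocyte/macrophage-like cells took 62.1% of these cells at 90 µm, 81.7% at 0 µm and 85.4% at 4 µm. Names such as T-like come from clusters rebuilt from marker genes, and naming thresholds were set after the data were seen. They left cluster 16 unnamed, with 1.02% of cells at 0 µm, 0.454% at 4 µm and 0.437% at 90 µm. Washing collects only loose cells, so these are shares of the cells it released.

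**Figure D1:**
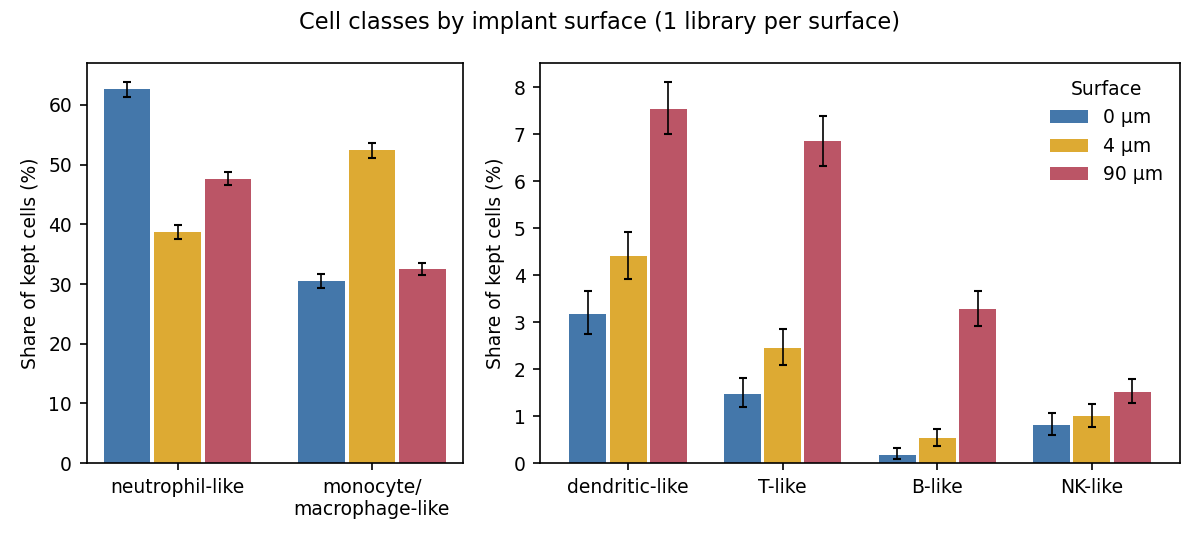
Share of kept cells (percent, y axis) in 6 cell classes for the 0, 4 and 90 µm libraries, 1 library of 5 pooled mice each; bars start at 0 and error bars are exact 95% Clopper-Pearson intervals, counting error only. T-like cells stood at 1.48%, 2.45% and 6.85%, and B-like cells at 0.183%, 0.530% and 3.28%.

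Gene levels are given as CPM, the counts of a gene scaled to the same UMI total in each class and library. In monocyte/macrophage-like cells, interferon response genes, which cells switch on after interferon signalling, were much higher at 90 µm than at 0 µm. All 15 measured members were higher by over 1.5-fold, with a median log2 ratio of 3.72 (3.36 to 4.05) at percentile 100 of 10000 random lists matched on mean expression. With both libraries weighted to one mix of clusters the median was lower, at 2.23. Monocyte-attracting chemokine genes, the pro-inflammatory list and the hypoxia and glycolysis list were also higher. Lower at 90 µm were Ltc4s, which makes the leukotriene C4 lipid mediator, Cx3cr1, the fractalkine receptor of resident and patrolling monocytes, and the growth factor gene Pdgfb. Ltc4s and Cx3cr1 are leading genes of cluster 2, which held a smaller part of the class at 90 µm, as given below.

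Ifit2, an interferon-induced RNA-binding protein, was at 160 CPM in 90 µm and 2.66 CPM in 0 µm monocyte/macrophage-like cells, 60.1-fold higher (35.1 to 113.1), although 92.3% of its 13 UMIs at 0 µm lay in 5 cells. Cxcl10, a chemokine that draws activated T cells, was 26.9-fold higher (22.7 to 32.1; 743 against 27.6 CPM), with 74.1% of its 135 UMIs at 0 µm in 5 cells. The surface protein gene Ly6i was 19.5-fold higher (15.5 to 24.8) and Ifit3 16.4-fold higher (12.8 to 21.4). The smallest difference on the list was in Ifi27l2a, 2.33-fold higher (2.29 to 2.37). Of 8 measured monocyte-attracting chemokines, 7 were higher, with a median log2 ratio of 1.74 (1.48 to 1.79) at percentile 100, or 1.22 at one mix of clusters. Ccl2, the main ligand of the monocyte receptor CCR2, was at 1396 against 275 CPM, 5.08-fold higher (4.81 to 5.37), with 46.3% of its 1345 UMIs at 0 µm in 5 cells. Its neighbours Ccl7 and Ccl12 were 7.02-fold (6.38 to 7.75) and 9.71-fold higher (7.61 to 12.6). Cxcl16 was the exception, 1.08-fold lower (1.01 to 1.15).

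All 13 measured pro-inflammatory genes were higher at 90 µm than at 0 µm in this class, 8 of them by over 1.5-fold, with a median log2 ratio of 0.73 (0.63 to 0.99) at percentile 100. Nos2, the inducible nitric oxide synthase, had 728 UMIs (53.4 CPM) at 90 µm and 0 UMIs in 1833 cells at 0 µm. Against a floor of 3 counts it was at least 87.1-fold higher, with an exact lower 95% limit of 70.7, and with Nos2 at that bound the list median stayed at 0.73. At one mix of clusters it was 0.53, and within cluster 14, a small one with 21 cells at 90 µm, it was -1.63. Cluster 3 held 89.9% of the 238 cells with a Nos2 UMI. Il1a was 11.6-fold higher (4.85 to 36.1) on 5 UMIs at 0 µm, and Il18 2.57-fold higher (2.19 to 3.04). Differences in Il1b and Tnf were small, with ratios of 1.26 (1.23 to 1.30) and 1.10 (0.965 to 1.26). In the hypoxia and glycolysis list, 10 of 12 members were higher, with a median log2 ratio of 0.69 (0.66 to 0.73) at percentile 100. At one mix of clusters that median was 0.40, and it was 0.71, 0.26 and 0.56 within clusters 1, 2 and 3 but -0.31 within cluster 14. Egln3, an oxygen-sensing prolyl hydroxylase, was 2.52-fold higher (2.20 to 2.89), the glucose transporter gene Slc2a1 2.14-fold (1.92 to 2.38) and Vegfa, which drives vessel growth, 2.06-fold (1.86 to 2.28). Gapdh, a glycolytic enzyme gene, was 1.09-fold lower (1.07 to 1.11).

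Genes of alternative activation, the macrophage state tied to repair, went both ways between 90 and 0 µm. The median log2 ratio was 0.27 (0.08 to 0.44; percentile 97.9) with 7 members higher and 5 lower, while the mean was -0.33. Arg1, which breaks down arginine, was 2.65-fold higher (2.51 to 2.80; 770 against 291 CPM) and Chil3 1.95-fold higher (1.79 to 2.13), but the lectin gene Mgl2 was 4.46-fold lower (1.90 to 11.0). Retnla was 39.9-fold lower (25.1 to 67.3), a ratio that rests on a handful of cells, since 98.5% of its 272 UMIs at 0 µm lay in 5 cells. Of 16 matrix and scar-associated macrophage genes, 11 were higher and 5 lower, with a median of 0.28 (0.24 to 0.35) at percentile 99.8, or 0.53 at one mix of clusters. Gpnmb was 14.2-fold higher (8.22 to 26.8) on 13 UMIs at 0 µm, the thrombospondin gene Thbs1 2.24-fold (2.15 to 2.33) and the osteopontin gene Spp1 1.53-fold (1.49 to 1.57). On the same list Pdgfb was 4.69-fold lower (4.09 to 5.39) and the fibronectin gene Fn1 2.05-fold lower (2.01 to 2.10). Ltc4s was 8.71-fold lower (7.30 to 10.4), Crip2 5.42-fold (4.54 to 6.50) and Cx3cr1 4.53-fold (4.07 to 5.05). Ltc4s, Crip2, Cx3cr1 and Fn1 are leading genes of cluster 2, which held 28.2% of the class at 0 µm and 12.3% at 90 µm. Arg1 and Chil3 are leading genes of cluster 3, which held 7.47% and 68.4%. The ratios of these genes are therefore not separated from the mix of clusters.

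Medians of the other lists were smaller for 90 over 0 µm in monocyte/macrophage-like cells. Complement and efferocytosis genes had a median log2 ratio of 0.17 (0.11 to 0.39) at percentile 92.7, or 0.68 at one mix of clusters, led by complement factor B, Cfb, 7.66-fold higher (6.14 to 9.68). Lists whose interval held 0 over the whole class were osteoclast and giant cell fusion genes at 0.05 (-0.21 to 0.30), lysosome and lipid handling at 0.01 (-0.05 to 0.07) and MHC class II presentation at 0.10 (-0.05 to 0.23). Within clusters 1, 2, 3 and 14, each taken alone, these medians were positive for osteoclast and giant cell fusion genes (0.24 to 0.88) and for lysosome and lipid handling (0.19 to 0.66). They were negative for MHC class II presentation (-0.46 to -0.08). Medians within clusters carry no interval here. Shifts of total scaling against median-of-ratios and TMM were -0.10 and -0.11 for this class and pair, larger than the -0.08 end of that range. Immediate-early and heat-shock genes, which can mark handling of the cells, stood at -0.01 (-0.14 to 0.04) and turned positive under both other scalings. Their medians were negative within each of the 4 clusters (-1.06 to -0.09), again without intervals. Proliferation genes had a median of -0.16 (-0.45 to -0.05), which turned to 0.03 when members with as little as 1 UMI were included and to 0.12 at one mix of clusters. Different clusters hold most of the class in the 2 libraries. Cluster 3, led by Ccl2, Ccl7, Chil3 and Plac8, held 68.4% of the class at 90 µm and 7.47% at 0 µm, while clusters 1 and 2 held 58.7% and 28.2% at 0 µm and 18.1% and 12.3% at 90 µm. The class also differed in depth, with a median of 1567 UMIs per cell at 0 µm, 3267 at 4 µm and 4033 at 90 µm.

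**Figure D2:**
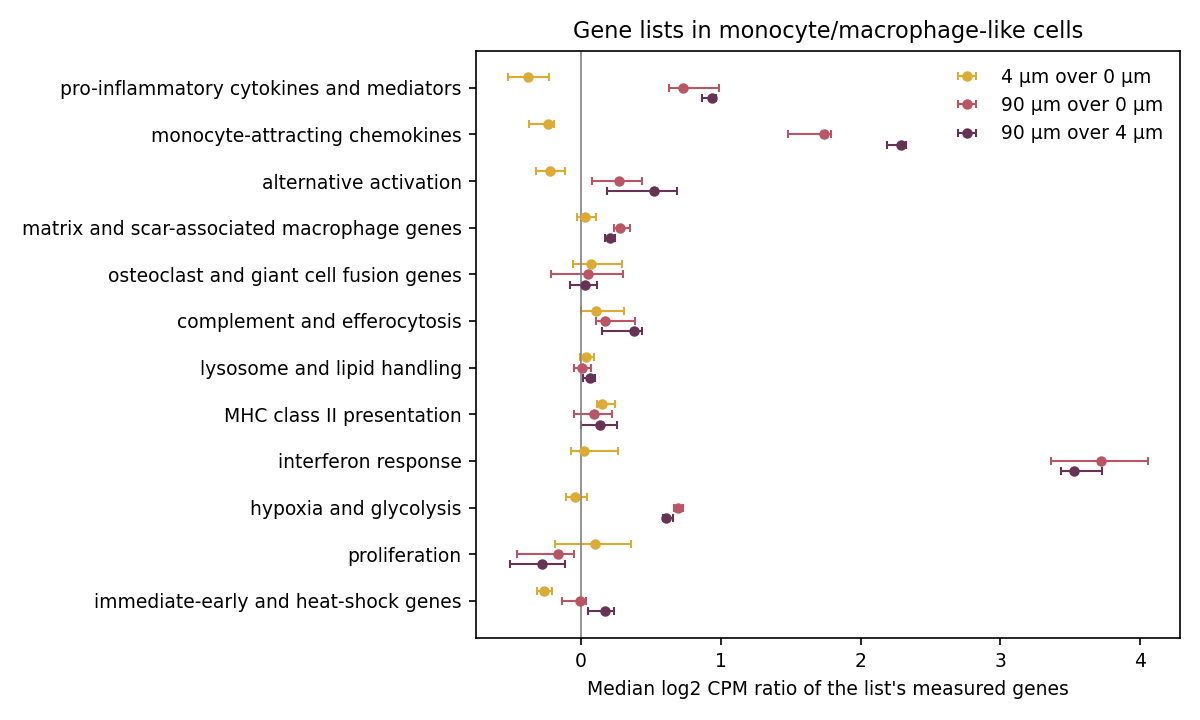
Median log2 CPM ratio (x axis) of the measured genes of 12 lists (y axis) in monocyte/macrophage-like cells for the 3 pairs of libraries; bars are 95% intervals from counting error only, and the line marks 0. Interferon response stood at 3.72 and 3.53 for 90 over 0 and 90 over 4 µm and at 0.02 for 4 over 0 µm, while immediate-early genes for 90 over 0 µm, at -0.01, turned positive under both other scalings.

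Interferon response genes were also higher at 90 than at 0 µm in neutrophil-like cells. All 14 measured members were higher by over 1.5-fold, with a median log2 ratio of 3.47 (3.33 to 3.57) at percentile 100. At one mix of clusters this median was far lower, as given below. The 4 lists read in this class were chosen for it after seeing the data. Gbp5, a guanylate-binding protein of inflammasome signalling, was at 268 against 3.06 CPM, 87.6-fold higher (61.6 to 129.1), with 45.2% of its 31 UMIs at 0 µm in 5 cells. The interferon-inducible GTPase genes Ifi47 and Igtp were 52.9-fold (44.6 to 63.3) and 31.9-fold higher (25.1 to 41.1). Ifit2 was 34.9-fold higher (25.1 to 50.02; 52.8% of its 36 UMIs at 0 µm in 5 cells) and Ly6i 30.9-fold (25.4 to 38.1). Cxcl9 had 231 UMIs at 90 µm and 0 at 0 µm, at least 64.7-fold higher at a floor of 3 counts, with an exact lower 95% limit of 52.2.

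Pro-inflammatory genes were lower over the whole neutrophil-like class, with 3 of 12 higher, 9 lower and a median log2 ratio of -0.29 (-0.32 to -0.25) at percentile 0.47 for 90 over 0 µm. The direction differed between clusters, with medians of -0.42, -0.46 and -0.04 in clusters 4, 6 and 7 but of 0.10, 0.45 and 0.60 in clusters 0, 5 and 8, which held 21.7%, 38.0% and 18.3% of the class at 90 µm. The neutrophil-attracting chemokine genes Cxcl2 and Cxcl1 were 1.88-fold (1.86 to 1.89) and 4.48-fold lower (3.43 to 5.94), while Nos2 was 8.60-fold higher (6.04 to 12.6). Il1b differed little, at 8717 CPM against 9448. Immediate-early and heat-shock genes had a median of -0.37 (-0.51 to -0.27) with 9 of 12 lower. Among them Nr4a1, an early response nuclear receptor, was 2.12-fold lower (2.03 to 2.22) and Atf3 2.11-fold lower (2.02 to 2.19). Hypoxia and glycolysis stood at 0.04 (-0.01 to 0.08), which turned negative under both other scalings. The lowest ratios by the naming rule were in Mrgpra2a, 2.67-fold lower (2.33 to 3.07), Mrgpra2b, 2.58-fold (2.40 to 2.77), Tmc6, 2.58-fold (2.22 to 3.01), and the adhesion molecule gene Ceacam1, 2.32-fold (2.11 to 2.55). Mrgpra2a and Mrgpra2b are close copies, so the split of UMIs between them is uncertain. Clusters 5 and 8, both led by interferon genes, held 2.29% and 1.28% of the class at 0 µm, and weighting both libraries to one mix of clusters lowered the interferon median to 0.94. Within cluster 8 that median was -0.32, and within the other clusters it lay between 1.14 and 2.02.

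**Figure D3:**
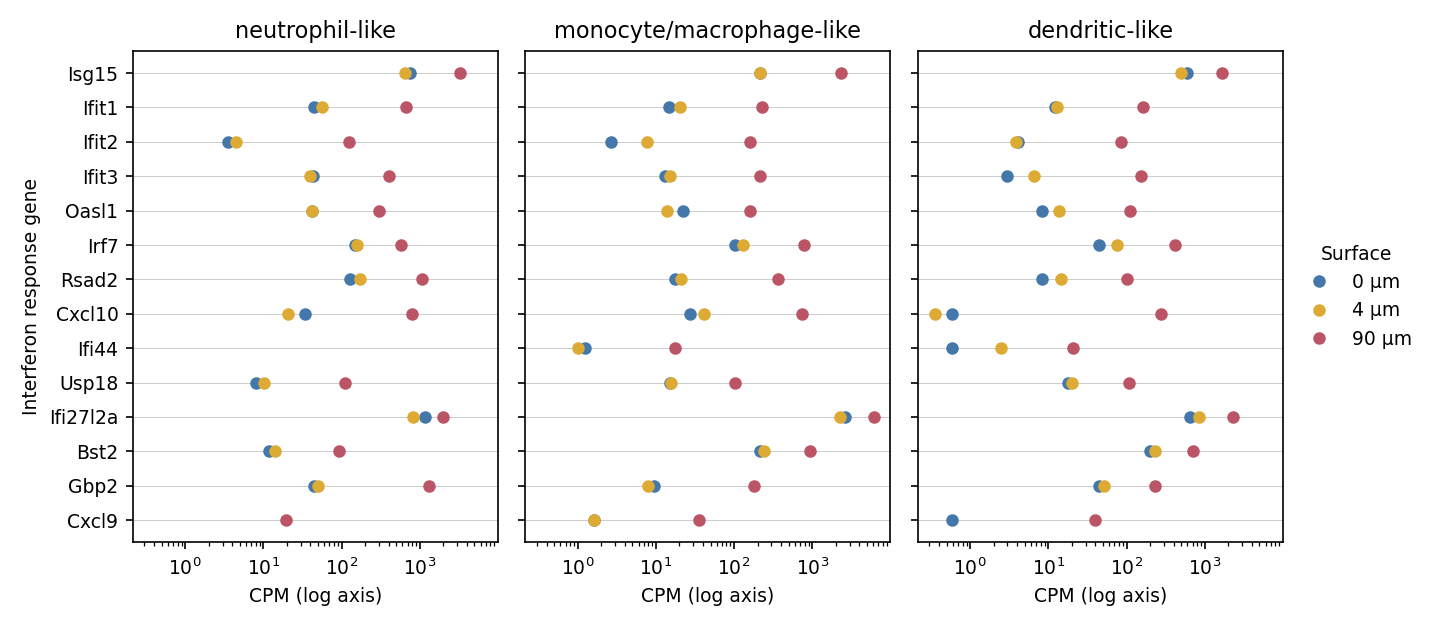
Level (CPM, log axis) of 14 interferon response genes in neutrophil-like, monocyte/macrophage-like and dendritic-like cells, 1 point per library; genes with 0 UMIs or not measured in a class have no point. Every gene drawn was higher at 90 µm than at 0 and 4 µm, for example Cxcl10 in monocyte/macrophage-like cells at 743, 27.6 and 41.5 CPM.

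The 90 µm library differed from the 4 µm library along much the same lists. In monocyte/macrophage-like cells, all 15 interferon response genes were higher by over 1.5-fold, with a median log2 ratio of 3.53 (3.43 to 3.73) at percentile 100, or 1.65 at one mix of clusters. Chemokine genes had a median of 2.29 (2.19 to 2.33), or 1.25 at one mix of clusters, with 7 of 8 higher, and Ccl2 stood at 1396 against 131 CPM, 10.6-fold higher (10.1 to 11.1). Ltc4s was 15.99-fold lower (13.7 to 18.8) at 90 µm than at 4 µm. It is a leading gene of cluster 2, which held 48.7% of the class at 4 µm and 12.3% at 90 µm. The lists for this class were fixed before the data were examined, so this library pair was read with the same genes.

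Ifit2 was 20.4-fold higher (16.97 to 24.8) at 90 than at 4 µm in this class, Cxcl10 17.9-fold (16.5 to 19.4), Ifi206, a DNA-sensor family gene, 15.3-fold (12.2 to 19.5), and the nucleotide kinase gene Cmpk2 14.2-fold (11.7 to 17.5). Part of the 4 µm signal lay in few cells, with 48.9% of 622 UMIs of Cxcl10 in 5 cells. Ccl7 was 9.95-fold higher (9.30 to 10.7), Ccl12 10.01-fold (8.64 to 11.6) and Ccl8 48.5-fold (22.0 to 133.4) on 6 UMIs at 4 µm. The pro-inflammatory list had a median of 0.94 (0.87 to 0.97) with 11 of 13 members higher, at percentile 100. Nos2 had 0 UMIs in 3459 cells at 4 µm, so it was at least 266.5-fold higher at 90 µm at that floor, with a lower limit of 216, and with this bound the median stayed at 0.94. At one mix of clusters it was 0.59, and within cluster 14 it was -1.18. Il1a was 16.1-fold higher (8.75 to 32.9) and Ptgs2, which makes prostaglandins, 6.29-fold (5.37 to 7.40). Tnf was 1.25-fold lower (1.15 to 1.36) and Cxcl1 1.27-fold lower (1.01 to 1.60). All 12 hypoxia and glycolysis genes were higher, with a median of 0.61 (0.59 to 0.66), led by Vegfa at 3.63-fold (3.35 to 3.94). This median was smaller at one mix of clusters, 0.29, and was 0.69, 0.28 and 0.32 within clusters 1, 2 and 3 but -0.34 within cluster 14, where 2 of 12 members were higher.

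Alternative activation genes had a median of 0.52 (0.19 to 0.69; percentile 99.9) for 90 over 4 µm, with Arg1 7.08-fold higher (6.72 to 7.46) and the carbonyl reductase gene Cbr2 3.33-fold lower (2.79 to 4.00). This median turned to -0.23 with both libraries weighted to one mix of clusters, and it was -0.43 within cluster 3. Matrix and scar-associated genes stood at 0.21 (0.17 to 0.24; percentile 99.0) with 9 of 16 higher, among them Thbs1 at 4.38-fold (4.23 to 4.52), while Pdgfb was 4.72-fold lower (4.19 to 5.32) and Fn1 1.96-fold lower (1.93 to 1.99). The matrix median was larger at one mix of clusters, 0.43, and within clusters 1, 2 and 3 it was 0.66, 0.51 and 0.61, with 14, 13 and 13 of 16 higher, against 0.09 within cluster 14. Complement and efferocytosis genes stood at 0.38 (0.15 to 0.43; percentile 99.1), or 0.05 at one mix of clusters, with Cfb 3.67-fold higher (3.33 to 4.05) and the C1q chain gene C1qa 1.82-fold lower (1.74 to 1.90). After Ltc4s, the lowest ratios were in Crip2, 9.596-fold lower (8.26 to 11.2), Adgre4, 6.16-fold (5.16 to 7.39), the sialophorin gene Spn, 6.06-fold (5.39 to 6.83), and Cx3cr1, 5.74-fold (5.24 to 6.30). Adgre4, Spn and Cx3cr1 are all carried by patrolling monocytes. Cx3cr1 is also a leading gene of clusters 1 and 2, and Ltc4s and Crip2 are leading genes of cluster 2. Both clusters were a smaller part of the class at 90 µm, so these ratios do not show a loss of patrolling monocytes. MHC class II presentation had a median of 0.14 (-0.00013 to 0.26) and osteoclast and giant cell fusion genes one of 0.03 (-0.08 to 0.12), against a mean of -0.06. Within each of clusters 1, 2, 3 and 14 the MHC class II median was negative (-0.82 to -0.20), opposite to the class, and that of osteoclast and giant cell fusion genes positive (0.17 to 0.67). Lysosome and lipid handling stood at 0.06 (0.02 to 0.10), which turned negative as a mean over cells, and at 0.42 to 0.66 within these clusters. Immediate-early genes at 0.17 (0.05 to 0.23) and proliferation genes at -0.28 (-0.50 to -0.11) turned to -0.02 and 0.25 at one mix of clusters. Cluster 3 held 6.76% of the class at 4 µm, where clusters 1 and 2 held 39.4% and 48.7%.

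In neutrophil-like cells, the 14 interferon response genes were again all higher at 90 than at 4 µm, with a median log2 ratio of 3.40 (3.24 to 3.53) at percentile 100. Gbp5 was 72.4-fold higher (50.6 to 107.5), Cxcl10 38.2-fold (32.8 to 44.7; 57.7% of its 168 UMIs at 4 µm in 5 cells), Ly6i 37.9-fold (29.7 to 49.1), Ifi47 37.0-fold (31.5 to 43.8) and Igtp 31.4-fold (24.1 to 41.7). Pro-inflammatory genes had a median of -0.43 (-0.47 to -0.40) with 8 of 12 lower, Cxcl2 by 2.49-fold (2.47 to 2.51) and Ccl4 by 1.98-fold (1.96 to 2.00). Hypoxia and glycolysis stood at -0.16 (-0.20 to -0.14) and immediate-early genes at -0.06 (-0.15 to 0.09), which turned to 0.05 at one mix of clusters. Within cluster 0 the pro-inflammatory median was 0.28, opposite to the class. The lowest ratios were in Ciart, a repressor of the circadian clock, 3.82-fold lower (3.20 to 4.58), Tmem251, 3.13-fold (2.81 to 3.50), Gclc, which makes glutathione, 3.13-fold (2.68 to 3.66), Atf3, 3.02-fold (2.90 to 3.14), and the proton pump gene Atp6v1c1, 2.94-fold (2.71 to 3.20). Clusters 5 and 8 held 3.02% and 1.49% of the class at 4 µm, and the interferon median at one mix of clusters was 0.63. Within these 2 clusters, which held 38.0% and 18.3% of the class at 90 µm, it was 0.40 and -0.18, the latter with 6 of 14 members higher, and within the other clusters it lay between 0.91 and 2.04. Other scalings shift all log2 ratios of this pair in neutrophil-like cells alike, since total scaling lies 0.33 above median-of-ratios and 0.27 above TMM scaling. For 90 over 0 µm these shifts are 0.16 and 0.13 in neutrophil-like cells and -0.10 and -0.11 in monocyte/macrophage-like cells, and for 4 over 0 µm in neutrophil-like cells -0.17 and -0.14.

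Between the 4 and 0 µm libraries, the interferon response list in monocyte/macrophage-like cells had a median log2 ratio of 0.02 (-0.07 to 0.27) over the whole class, but went both ways within clusters. It was 0.61, 0.82 and 1.05 in clusters 1, 3 and 14, each with 13 of 15 members higher at 4 µm, and -0.62 in cluster 2, with 3 of 15 higher. At one mix of clusters it was 0.48. Mmp12, an elastin-degrading protease, was 3.73-fold higher at 4 µm (2.95 to 4.77; 58.6 against 15.7 CPM), but on few cells, as 40.3% of its 878 UMIs at 4 µm and 46.8% of its 77 at 0 µm each lay in 5 cells. Arg1 was 2.67-fold lower at 4 µm (2.49 to 2.87) and Ccl2 2.09-fold lower (1.95 to 2.24). The pro-inflammatory list had a median of -0.38 (-0.52 to -0.23) and the chemokine list one of -0.23 (-0.37 to -0.19) at percentile 1.05. Neither held under every setting, since keeping doublets moved the first to -0.03 and one mix of clusters turned the chemokine list to 0.03.

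Other high ratios at 4 over 0 µm in this class were in Lyz1, a lysozyme gene with a close copy, at 3.11-fold (2.47 to 3.96) with 58.0% of its 81 UMIs at 0 µm in 5 cells, Tmem37 at 2.60-fold (2.16 to 3.15), the growth factor gene Igf1 at 2.13-fold (1.81 to 2.52) and Ltc4s at 1.84-fold (1.67 to 2.02). Lower were Thbs1, 1.96-fold (1.87 to 2.05), Vegfa, 1.76-fold (1.57 to 1.98), and Retnla, 55.5-fold (33.0 to 100.5), again a handful of cells. Of 13 pro-inflammatory genes 9 were lower, but Nos2 and Il6 had at most 3 UMIs in both libraries, and without them 7 of 11 were lower with a median of -0.36. Ptgs2 was 3.38-fold lower (2.75 to 4.15), while Tnf was 1.38-fold higher (1.21 to 1.57). Alternative activation stood at -0.22 (-0.32 to -0.11), turning to 0.09 at one mix of clusters, and immediate-early genes at -0.26 (-0.31 to -0.21) with 11 of 12 lower. MHC class II presentation, at 0.15 (0.11 to 0.25), and complement and efferocytosis, at 0.11 (0.0018 to 0.31), were higher, the latter with C1qa at 1.76-fold (1.65 to 1.88). Intervals that held 0 belonged to matrix and scar-associated genes, at 0.03 (-0.03 to 0.11), osteoclast and giant cell fusion genes, at 0.07 (-0.06 to 0.29), lysosome and lipid handling, at 0.03 (-0.0040 to 0.10), hypoxia and glycolysis, at -0.04 (-0.10 to 0.04), and proliferation, at 0.10 (-0.18 to 0.36).

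Neutrophil-like cells at 4 µm had higher levels of Ciart, 1.88-fold (1.62 to 2.18), the copper transporter gene Slc31a2, 1.83-fold (1.64 to 2.03), Mfsd1, 1.77-fold (1.62 to 1.94), and Ifit1bl2, 1.77-fold (1.57 to 1.98), than at 0 µm. Ftl1-ps1, a copy of the ferritin light chain gene whose UMIs are uncertain, was 1.84-fold higher (1.73 to 1.95). Hist1h2bc was 2.36-fold lower (2.02 to 2.75), the early response gene Egr1 1.90-fold (1.79 to 2.02), Itpkb 1.86-fold (1.64 to 2.11), the splicing factor gene Isy1 1.86-fold (1.64 to 2.11) and the microRNA host gene Mir142hg 1.80-fold (1.54 to 2.12). The hypoxia and glycolysis list had a median of 0.28 (0.21 to 0.33) with 10 of 12 higher, and the pro-inflammatory list one of 0.23 (0.06 to 0.32) with 7 of 12 higher. The latter was -0.12, 0.01 and 0.02 within clusters 0, 4 and 6, the largest at 0 and 4 µm, and between 0.24 and 0.50 within clusters 5, 7 and 8. Immediate-early genes stood at -0.22 (-0.27 to -0.14) and interferon response at 0.11 (-0.04 to 0.19), or 0.05 without Cxcl9, which had 0 UMIs in both.

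Gene levels of T-like cells were compared between 90 and 4 µm alone, because the 0 µm library held 89 of them, under the limit of 100 set in advance. Naive or central memory T cell-like cells, which circulate before or between encounters with antigen, were 47.7% of T-like cells at 90 µm (43.7 to 51.8), 18.5% at 4 µm (12.9 to 25.4) and 2.25% at 0 µm (0.273 to 7.88). Interferon response genes were higher in T-like cells too, with all 13 measured members higher in 90 than in 4 µm and a median log2 ratio of 1.61 (1.35 to 1.94) at percentile 100, or 2.09 at one mix of clusters. Of 12 cytotoxicity genes 9 were lower at 90 µm, with a median of -0.77 (-1.01 to -0.65), or -0.59 at one mix of clusters, and a mean of -0.30.

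Regulatory T cell-like cells were 11.2% of T-like cells at 0 µm (5.52 to 19.7), 8.02% at 4 µm (4.34 to 13.3) and 6.37% at 90 µm (4.57 to 8.61). They numbered 10, 13 and 39 among 6004, 6603 and 8932 kept cells, so they were not scarcer among all cells at 90 µm. Shares of T-like cells sum to a whole, so the larger naive subset at 90 µm lowers the others. CD8 T cell-like cells were 13.5%, 16.7% and 3.27%, CD4 T cell-like cells 20.2%, 7.41% and 6.37%, gamma-delta T cell-like cells 13.5%, 3.09% and 4.08%, and proliferating ones 2.25%, 1.85% and 1.63%. The CD8 T cell-like share is not the share of all CD8 T cells. Leading genes of cluster 10 include Cd8a and Cd8b1 beside the naive cell markers Lef1 and Tcf7. Subclusters that met no naming rule, set after seeing the data, held 37.1% at 0 µm, 44.4% at 4 µm and 30.6% at 90 µm. Cluster 10 held 53.6% of T-like cells at 90 µm, 40.1% at 4 µm and 5.62% at 0 µm, and cluster 11 held 39.4%, 50% and 83.1%. After thinning to 1000 UMIs per cell, which left out 1, 4 and 6 cells, a UMI of the regulatory T cell gene Foxp3 was seen in 6.82% (2.54 to 14.3), 6.96% (3.53 to 12.1) and 5.12% (3.50 to 7.18) of T-like cells at 0, 4 and 90 µm. Unthinned shares were 12.4%, 14.2% and 9.48%. Cd8a was seen in 15.9%, 22.8% and 15.02% (unthinned 24.7%, 43.8% and 35.6%), Cd4 in 4.55%, 6.96% and 7.10% (unthinned 27.0%, 21.0% and 21.4%), and the gamma-delta receptor gene Trdc in 6.82%, 0.633% and 1.98% (unthinned 12.4%, 1.85% and 5.23%). In monocyte/macrophage-like cells, with 598, 614 and 386 cells left out, at most 1 cell per library had a UMI of each, 0.081% at most. Unthinned, that background was 0.172% at most, at median depths of 1567, 3267 and 4033 UMIs against 5397, 5590 and 4788 in T-like cells.

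Among interferon response genes in T-like cells, Isg15 was 6.08-fold higher (4.83 to 7.76) at 90 than at 4 µm. Spp1, abundant in the myeloid classes, was also 26.6-fold higher (7.26 to 221) in T-like cells, on 193 against 2 UMIs, and Il1b 1.62-fold higher (1.30 to 2.04), so free RNA is not excluded for these genes. Hypoxia and glycolysis had a median log2 ratio of 0.71 (0.58 to 0.89), with Slc2a1 2.31-fold higher (1.60 to 3.45), and immediate-early and heat-shock genes one of 0.60 (0.36 to 0.74). In the latter list 11 of 12 members were higher, at percentile 100, and the mean was 1.28, with Hspa1a and Hspa1b highest. Such genes can mark handling of the cells, so a difference in handling between these 2 libraries is not excluded. The naive and central memory list stood at 0.31 (0.14 to 0.58), with the lymph node homing receptor gene Ccr7 1.85-fold higher (1.60 to 2.13). T cell activation stood at 0.32 (0.16 to 0.47), with Cd69 1.82-fold higher (1.42 to 2.36). Inhibitory receptors had a median of -0.57 (-0.83 to -0.31), with the checkpoint receptor gene Lag3 4.41-fold lower (3.18 to 6.14). In the cytotoxicity list, Nkg7 was 2.60-fold lower (2.42 to 2.79) while the granzyme gene Gzmb was 2.15-fold higher (1.86 to 2.49). Gzma, another granzyme gene, was 22.5-fold higher (9.57 to 69.7) on 5 UMIs at 4 µm, with 65.5% of its 409 UMIs at 90 µm in 5 cells. Type 1 helper genes stood at -0.43 (-0.57 to -0.14), with the chemokine receptor gene Cxcr3 2.44-fold lower (2.04 to 2.92) and Ifng at a ratio of 0.683 (0.431 to 1.11). MHC class II genes, which mouse T cells scarcely make, had a median of -1.05 (-1.40 to -0.88) with all 8 lower, which turned to 0.28 at one mix of clusters. That mix, like the others of T-like cells, leaves out cluster 17, which had 16 cells at 4 µm and whose leading genes include Foxp3. Intervals that held 0 belonged to type 2 helper, at 0.57 (-0.16 to 1.51) but -0.46 for Gata3, its only member with at least 200 UMIs, and -0.19 at one mix of clusters, type 17, at 0.19 (-0.06 to 0.54), regulatory T cell, at 0.04 (-0.22 to 0.39) with a mean of -0.04 but 0.64 at one mix of clusters, without cluster 17, follicular helper, at 0.28 (-0.06 to 0.44), and proliferation genes, at 0.24 (-0.03 to 0.59) but -0.22 as a mean over cells. Il5 had 0 UMIs at 4 µm and 25 at 90 µm, at least 2.29-fold higher at a floor of 3 counts, with an exact lower 95% limit of 1.73, while Il17a had 0 and 2 UMIs and allows no fold. Total scaling of this pair lies 0.08 below median-of-ratios and 0.11 below TMM scaling.

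Positions are given for mm10 (GRCm38), 1-based, from the GENCODE annotation, each entry spanning a protein-coding gene. Ifit2 (ENSMUSG00000045932) lies on chromosome 19 from 34550694 to 34576419, Cxcl10 (ENSMUSG00000034855) on chromosome 5 from 92346638 to 92348889, and Gbp5 (ENSMUSG00000105504) on chromosome 3 from 142493978 to 142522344. Chromosome 11 carries Nos2 (ENSMUSG00000020826) from 78920787 to 78960254, Ccl2 (ENSMUSG00000035385) from 82035571 to 82037453, Ccl7 (ENSMUSG00000035373) from 82045712 to 82047525, Ccl12 (ENSMUSG00000035352) from 82101845 to 82103400, and Ltc4s (ENSMUSG00000020377) from 50236461 to 50238616. Arg1 (ENSMUSG00000019987) lies on chromosome 10 from 24915221 to 24927484, Mmp12 (ENSMUSG00000049723) on chromosome 9 from 7344381 to 7369499 and Cx3cr1 (ENSMUSG00000052336) on chromosome 9 from 119901616 to 120069879.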

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

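Of the tests in this part, those of free RNA without 3 shared markers, of cluster mix for the interferon genes, of T-like cells outside the naive subset and of B-like per naive T-like cells were chosen only after the result was seen. Pro-inflammatory cytokines and mediators stood out because their direction over a whole class differed between cell classes. For 90 over 0 µm, the list median log2 ratio was 0.7276 in monocyte/macrophage-like and -0.2912 in neutrophil-like cells. For 90 over 4 µm it was 0.9385 and -0.4349. The difference between the classes was not tested, since each surface has 1 library. It did not hold within every cluster: for 90 over 0 µm the neutrophil-like median was 0.10, 0.45 and 0.60 in clusters 0, 5 and 8, and the monocyte/macrophage-like one -1.63 in cluster 14.

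Interferon response genes were higher at 90 µm in every class measured, which could come from free RNA, from another mix of clusters, from some of the 5 pooled mice or from a response across all of them. In 90 µm T-like cells the observed level was 0.6678 of the most that free RNA brings when all markers set that bound, but Ly6c2, a marker that T cells also express, set it; without Ly6c2, Ccr2 and Plac8 the median was 11.43, with 11 of 13 members above 3, so free RNA is an unlikely source under the second bound alone. Across 8 neutrophil-like and monocyte/macrophage-like clusters not led by interferon genes the lowest median log2 ratio of 90 over 0 µm was 1.236, the lowest in dendritic-like clusters 2.893 and in T-like ones, for 90 over 4 µm, 1.59, so another mix of clusters alone does not account for it, although within neutrophil-like clusters 5 and 8, which interferon genes lead, it was 1.141 and -0.3239. After thinning, 88.74% of 90 µm and 55.5% of 0 µm neutrophil-like cells had a UMI of the list, against 96.7% and 77.81% of monocyte/macrophage-like cells, and a response in some of the mice and one in all of them cannot be told apart, because the pooled cells carry no mouse of origin and the 0 µm shares are high. Infection, interferon made at the 90 µm surface and differences in handling of that library might each give this pattern.

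Monocyte-attracting chemokine genes in 90 µm monocyte/macrophage-like cells might be higher because cluster 3 is larger there or because many 0 µm cells of this class have few UMIs. At one mix of clusters the list median log2 ratio of 90 over 0 µm was 1.222, against 1.737 over the whole class, so the mix alone does not account for all of the difference. Cluster 3 is led by Ccl2 and Ccl7, members of this list, so one mix lowers the median by construction. The drop therefore does not show how much of the difference the mix accounts for. Without cluster 1, the cluster of fewest UMIs, the median was 1.481. A difference in the state of these cells therefore remains possible, in a single library of each surface.

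T-like cells were a larger share at 90 µm, and many were naive or central memory T cell-like, which could come from lymph node tissue or blood taken along, since the mammary fat pad holds a lymph node. Outside that subset, T-like cells were still 2.472 times the share of kept cells at 0 µm (1.945 to 3.171). Of these, 187 of 320 cells at 90 µm and 33 of 87 at 0 µm lay in unnamed subclusters, which could hold naive cells too. The lower neutrophil-like share at 90 µm also raises this ratio. It therefore does not settle whether carry-over of naive cells alone accounts for the difference. At 90 µm there was 1.003 B-like cell per naive or central memory T cell-like cell. Hemoglobin UMIs, which unlysed blood would bring, numbered 8 at 0 µm, 12 at 4 µm and 3 at 90 µm, so they show no excess of red cells at 90 µm. Lymphocytes from node or blood and lymphocytes drawn into the capsule cannot be told apart, because both bring B-like and naive cells together and no blood or node library was measured.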

How the results depend on the processing

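No paired analysis was possible because each surface has 1 library, and for the same reason no library could be left out in turn. The stricter filter for lists, one mix of clusters, and the neutrophil-like, dendritic-like and T-like lists were chosen after seeing the data, as was the set of main results below. A result is called the same when its value stays within its 95% counting interval, moved when it leaves it, and reversed when it lies on the other side of no difference from an interval that excludes it. All 15 share ratios stayed the same with 15 components, resolutions 0.5 and 2 and no cell filter, and all 74 list medians with 1 UMI added. With the stricter filter, the share ratio was 0.7123 for neutrophil-like cells (90 over 0 µm) and 1.984 and 1.229 for monocyte/macrophage-like cells (4 over 0 and 90 over 0 µm). With classes set by cell, monocyte/macrophage-like share ratios were 1.846, 1.22 and 0.6611 (4 over 0, 90 over 0, 90 over 4 µm) and dendritic-like ones 1.519 and 1.152 (90 over 0, 90 over 4 µm). Next come list median log2 ratios in monocyte/macrophage-like cells. Pro-inflammatory cytokines and mediators: 4 over 0 µm, -0.02959 with doublets kept and -0.2132 at one cluster mix; 90 over 0 µm, 0.6082 as mean over cells and 0.5261 at one cluster mix; 90 over 4 µm, 1.042 by median of ratios, 1.038 by TMM, 0.5887 at one cluster mix and 0.817 with at least 200 UMIs. Monocyte-attracting chemokines: 4 over 0 µm, -0.1593 as mean over cells and, reversed, 0.03234 at one cluster mix. For 90 over 0 µm they stood at 1.841 (median of ratios), 1.844 (TMM), 2.294 (mean over cells) and 1.222 (one cluster mix), and for 90 over 4 µm at 2.394, 2.39, 2.512 and 1.249. Interferon response: 4 over 0 µm, 0.4408 as mean over cells and 0.4813 at one cluster mix, which gave 2.234 for 90 over 0 and 1.647 for 90 over 4 µm. Interferon response in neutrophil-like cells, 4 over 0 µm: 0.2745 (median of ratios), 0.2515 (TMM), 0.2088 (mean over cells) and 0.1924 (one cluster mix). For 90 over 0 µm it was 3.307 by median of ratios, 0.9379 at one cluster mix and 3.209 with at least 1 UMI, and for 90 over 4 µm 3.068 by median of ratios, 3.126 by TMM and 0.6286 at one cluster mix. Clusters 5 and 8 of this class are led by interferon genes, so one cluster mix lowers this difference by construction, without removing it. Other reversals in monocyte/macrophage-like cells at one cluster mix were alternative activation (0.09366 for 4 over 0, -0.229 for 90 over 4 µm), proliferation (0.1177 for 90 over 0, 0.2452 for 90 over 4 µm) and immediate-early and heat-shock genes (-0.01757 for 90 over 4 µm), and in T-like cells MHC class II presentation (0.2753 for 90 over 4 µm). Lysosome and lipid handling median log2 ratio, 90 over 4 µm, reversed to -0.00341 as mean over cells, and proliferation, 90 over 0 µm, to 0.0295 with at least 1 UMI. For all of these but the neutrophil-like cluster mix, the cause was not tested. Over all list medians and named genes, one cluster mix left 35 the same, moved 92 and reversed 7; mean over cells left 80, moved 53 and reversed 1; median of ratios left 94 and moved 40; TMM left 99 and moved 35. Keeping doublets left 152 and moved 3, the stricter filter left 151 and moved 4, at least 200 UMIs left 66 and moved 8, and at least 1 UMI left 69, moved 4 and reversed 1. T subclusters at resolutions 0.5 and 2 each left 5 and moved 1, and shares with a UMI moved in 4 of 12 cases at 2000 UMIs and in 8 unthinned. Depth limits genes with few UMIs: at 0 µm, with 89 T-like cells and a median of 1567 UMIs in monocyte/macrophage-like cells, lower levels of Nos2 or Il6 were not detectable.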

Other observations

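No test in this part was planned before its result was seen. In dendritic-like cells, with 191, 291 and 674 cells at 0, 4 and 90 µm, 4 lists were read. Interferon response had a median log2 ratio of 3.59 (3.08 to 3.86) for 90 over 0 µm and 2.82 (2.42 to 3.07) for 90 over 4 µm, all 15 members higher in both, and 0.20 (0.02 to 0.46) for 4 over 0 µm. Cxcl10 had 1 UMI at 0 µm, 1 at 4 µm and 2026 at 90 µm, 473-fold higher at 90 than at 0 µm (84.8 to 18700). Isg15 was 2.84-fold higher (2.66 to 3.03) and Ifit3 53.0-fold (22.6 to 164) for the same pair. Hypoxia and glycolysis stood at 0.61 (0.48 to 0.66) for 90 over 0 µm, 0.76 (0.67 to 0.84) for 90 over 4 µm and -0.18 (-0.26 to -0.05) for 4 over 0 µm.

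The pro-inflammatory list was lower in dendritic-like cells at 90 µm, at -0.62 (-0.76 to -0.31) against 0 µm and -0.44 (-0.75 to -0.32) against 4 µm, and stood at -0.14 (-0.28 to 0.07) for 4 over 0 µm, where the mean was 0.09. Ccl3 was 5.18-fold lower (4.22 to 6.36) and Ccl4 4.996-fold lower (4.48 to 5.57) at 90 than at 0 µm. Of 12 measured members, 4 were higher and 8 lower at 90 than at 0 µm. The higher ones were Nlrp3, Cxcl3, Il18 and Nos2, the last with 0 UMIs at 0 and 4 µm and 35 at 90 µm. MHC class II presentation was at 0.27 (0.22 to 0.33) for 4 over 0 µm, -0.13 (-0.21 to -0.03) for 90 over 0 µm and -0.27 (-0.36 to -0.18) for 90 over 4 µm. These medians lay at percentiles 99.99, 23.4 and 1.22 of random lists, with 7, 4 and 3 of 10 members higher. The 90 over 0 µm value is thus within the range of random lists.

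Some signals lay in very few cells. In 0 µm T-like cells, Il17a had 28 UMIs, 89.3% of them in 5 cells, and Il17f had 20 UMIs, against 0 of either at 4 µm and 2 and 4 at 90 µm. Trdc had 33, 6 and 73 UMIs in 11, 3 and 32 T-like cells at 0, 4 and 90 µm, or 12.4%, 1.85% and 5.23% of them. The 5 cells with most UMIs held 72.7% at 0 µm and 32.9% at 90 µm. These shares come from unlike numbers of cells, so they do not compare how widely Trdc was spread. Col1a1, a fibroblast gene, had 95 UMIs in 4 monocyte/macrophage-like cells at 4 µm, 201 UMIs in 9 at 90 µm and 0 at 0 µm.

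The libraries also differed in the median share of mitochondrial UMIs per barcode, at 0.136% for 0 µm, 0.738% for 4 µm and 0.404% for 90 µm.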
